A study of Mus musculus with 225 samples.

How the data were processed

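The series holds 225 single cells of mouse lung epithelium, each captured in a microfluidic chamber (Fluidigm C1), reverse-transcribed and amplified with a Smart-Seq kit over 21 PCR cycles with ERCC spike-in RNA, and sequenced as a library of its own. Per the labels' protocols, neuroendocrine (NE) cells were marked with the fluorescent protein ZsGreen in Ascl1-CreERT2 or CGRP-CreERT2 mice, in which tamoxifen switches on a reporter in cells that use the Ascl1 or Calca locus. The mice were 2 to 3 months old, received 4 mg of tamoxifen 4 to 7 days before collection, and were pooled, 6 to 10 to a round. Tamoxifen is recorded for the ZsGreen-positive cells only, and the number of pooled mice is not recorded for the Lyz2 rounds. Tamoxifen is therefore not separated from the sort, also within the Ascl1 rounds. Other epithelial cells were ZsGreen-negative cells of littermates without CreERT2, or of Lyz2-Cre mice, in which alveolar type 2 (AT2) cells carry the reporter and were therefore meant to be sorted away. The genotype label of the littermates' cells names Ascl1-CreERT2 although the protocol describes them as lacking it, and this was left unresolved. Lungs were depleted of CD31 and CD45 cells with beads and sorted for EpCAM-positive, CD31-, CD45- and F4/80-negative live cells, and cells with little amplified cDNA had been left out before deposit.

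Estimated counts were made by the authors with kallisto 0.43.0, per the submitters' processing notes, which also name CASAVA 1.8.2, FastQC, cutadapt and Trim Galore. The genome build is not given in the sources used here, and no coordinates are reported. The deposited table of estimated counts has 32886 transcripts, 92 ERCC spikes and 1 ZsGreen transcript, and 91.5% of its values are whole numbers (56.1% of those above 0), compared exactly. The deposited TPM table, made by the authors for the same transcripts and ZsGreen, sums to 1000000 in every cell, so it keeps no depth. Transcripts were added up by the gene symbol the tables pair with each transcript, which gave 24172 symbols, 19568 of them with a count in some cell. Of the transcripts, 32428 were found in the RefSeq gene table of the reference, 30559 under the same symbol. kallisto divides reads between near-identical sequences by a model, so single members of pairs such as Lyz1 and Lyz2, Calca and Calcb, or Hspa1a and Hspa1b are uncertain. Smart-Seq libraries do not mark strand, so reads of a gene and of an overlapping antisense gene cannot be separated.

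Cell types are the authors' deposited assignments: 217 cells carry 1 type and 8 carry a pair of types. These assignments were made from the expression of the same cells, so differences between types are not independent of the grouping, and Ascl1 and Calca were also the loci that drove the sort. Cells are not replicates. The replicate was the collection round, read from a date-like code in the sample titles; that this code marks a round is an inference, and 9 rounds resulted. Counts were summed over the cells of a round and type (or a round and sort), rounded to whole numbers after summing, and kept where at least 2 cells contributed. No pair of cells had a correlation of log2(TPM + 1) above 0.658, so none was treated as a duplicate.

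The sums were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10, the quasi-likelihood F test, and Benjamini-Hochberg (BH) adjustment with a threshold of 0.05. The fit of the sorts had 9 residual degrees of freedom and a common dispersion of 2.15, the joint fit of NE, AT2, ciliated and club cells 12 and 2.68, the fit of NE cells by driver 5 and 2.25, and the fit of ciliated cells by mouse line 2 and 1.69. NE-enriched and NE-depleted genes had an adjusted p under 0.05 and a log2 fold change beyond 1 in the same direction against AT2, ciliated and club cells. Gene lists were tested with limma 3.58.1 (camera on voom values) with a preset inter-gene correlation of 0.01 and again with an estimated one, BH-adjusted over the lists of at least 3 tested genes. Levels per round are log2 CPM (counts scaled to a total of 1000000) with a prior count of 2. Shares of cells detecting a gene used a TPM of at least 1, with exact Clopper-Pearson intervals at a confidence of 0.95; where no cell detected a gene, the share allowed is 3 cells of the total. Single values were compared over rounds with two-sided exact permutation tests. Where a group had no counts of a gene, the fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts the ratio of summed CPM is given with its counting interval. Amplified reads carry no molecular identifiers, so such intervals, bounds and floors cover counting error only.

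The design, the tests, the alternatives and 25 gene lists were fixed before the data were examined. The lists hold markers of NE, AT2, club, ciliated, stromal, alveolar type 1 (AT1), basal, tuft, ionocyte, immune, endothelial and erythroid cells, and genes of neuropeptides and hormones, dense core granules, synaptic vesicles, small transmitters, sensory channels, Notch receptors and targets, Notch ligands, the Rb pathway, p53 targets, proliferation, small cell lung cancer, MHC class II and the stress of tissue dissociation. Genes were named by a rule fixed at the same time: among genes called, with every round of the higher group above every round of the lower, and detected in at least 50% of cells of the higher group, the 12 with the largest fold change in each direction for the sorts and the conjunctions and the 5 largest for other comparisons, passing over unnamed gene models, Y-linked genes and Xist. For the conjunctions the smallest of the 3 fold changes ranked the genes. Beyond these, 2 to 4 members of a list with its smallest adjusted p are named, and any member of the Notch, Rb and p53 lists.

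Round was also fitted as a block. Sums from the same round share a collection batch. Over the 10 pairs of sums of different type from the same round, deviations from the type means had a median correlation of 0.0448. The median was -0.0043 over 79 pairs from different rounds. The highest value was 0.152, for AT2 and ciliated cells of Lyz2 round 1, against at most 0.084 between different rounds, so a shared batch effect is not excluded. The Ascl1 rounds hold both sorts and the CGRP rounds hold NE cells alone, so the blocked comparison of the sorts, and of NE with AT2 and ciliated cells, rests on Ascl1 rounds 1 and 2 as within-round values. No round holds sums of both NE and club cells, so blocked values against club cells, and those of the conjunctions, are indirect, through the other types. Other alternatives were DESeq2 1.42.0, RLE scaling, ERCC sums as library sizes, no count filter, limma on log2(mean TPM + 1), a minimum of 1 or 5 cells per sum, leaving out each round, other detection thresholds, and cells thinned to 1109900 gene counts, which left out 23 cells (14 NE, 6 ciliated, 3 club). With ERCC scaling the median log2 difference of all genes was 0.68 between the sorts and 0.51, 0.68 and 0.94 between NE cells and AT2, ciliated and club cells, against 0.01, 0.00, 0.03 and 0.34 with TMM scaling.

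The fits across genes were also run on simulated counts of the same size in which 200 genes were changed; for AT2 against ciliated cells no gene was changed. For the sorts, edgeR called 0%, 8.96% and 31.3% of genes changed 4-, 16- and 64-fold and 0 of 12495 unchanged genes, while DESeq2 called 15.9%, 49.3% and 84.4% but also 219 unchanged genes. For Ascl1- against CGRP-labelled NE cells edgeR called 3.08% of genes changed 64-fold and 0 of 12005 unchanged ones, and DESeq2 called 55.4% and 305. In the joint fit of types, camera gave p = 4.54e-16 for a changed list and 0.174 for an unchanged one. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.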

Results

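Transcripts were measured in single cells of adult mouse lung, 100 of them from the ZsGreen-positive sort that marked pulmonary neuroendocrine cells and 125 from ZsGreen-negative epithelial sorts. NE cells are rare airway cells that store peptides in dense core granules and lie in contact with nerves. The authors' types among the cells with 1 assigned type were 92 NE, 54 AT2, 43 ciliated, 17 club and 11 stromal cells. AT2 cells make surfactant, ciliated cells carry motile cilia and club cells secrete into the airway lumen. The 8 cells given a pair of types were all from the ZsGreen-positive sort: 3 NE and ciliated, 2 NE and AT2, 2 NE and club, and 1 NE and stromal. NE cells came from Ascl1 rounds 1 and 2 and CGRP rounds 1 to 5. Other cells came from Ascl1 rounds 1 and 2 and Lyz2 rounds 1 and 2.

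**Figure D1:**
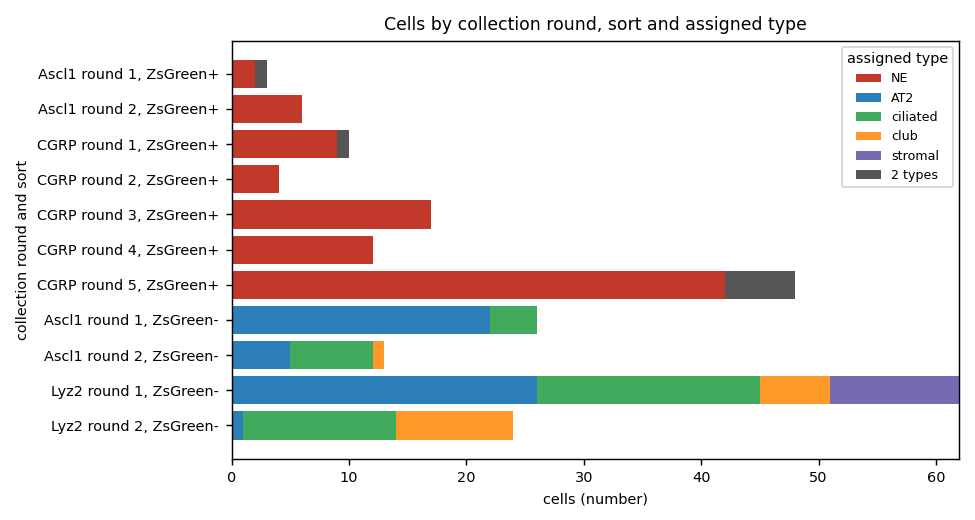
Number of cells on the x axis for each collection round and sort on the y axis, with bar segments coloured by assigned type and cells given a pair of types in grey. CGRP round 5 holds 42 NE cells, and the 11 stromal cells are all in Lyz2 round 1.

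Cells held 395123 to 10685000 gene counts, with a median of 2530340. ERCC spikes took 7.79% to 73.1% of a cell's counts, with a median of 27.5%. Between 2025 and 7016 genes per cell had a TPM of at least 1. Single genes took very different shares by type: the most abundant gene held a median 42% of TPM in AT2 cells and 70.3% in club cells, against 2.93% in NE cells and 2.84% in ciliated cells. Sums over a round and type ranged from 1993339 counts in CGRP round 2 to 111587802.

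The reporter and the markers were read first as a check of the labels. All 100 ZsGreen-positive cells held the ZsGreen transcript at a TPM of at least 1, with values of 5.52 to 17776. Of the 125 ZsGreen-negative cells, 43 also reached a TPM of 1, with a maximum of 1647 and a median of 0. NE cells detected a mean of 12.6 of the 16 NE markers and 2.17 of the 14 AT2 markers, and AT2 cells detected 13.5 of the AT2 markers. Markers of other types were present at low level: Scgb1a1, the main club cell secretory protein, had a TPM of at least 1 in 87% of NE cells at a median of 18.1, and Sftpc, the AT2 surfactant gene, in 40.2%. Ptprc, which marks all leukocytes, was found in 0 of 92 NE cells, which allows a share of up to 3.26%.

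The sorts were compared to find what distinguishes NE cells from the epithelium around them. Among the genes named for their size was Pcsk1 of the dense core granule list. This gene, the convertase that cleaves prohormones, was at least 140860-fold higher, with 9.99 ± 0.84 log2 CPM (SD, n = 7 rounds) in NE rounds and 0 counts in the 4 rounds of other cells (adjusted p = 6.67e-05). Scg2, a granin of dense core granules, was at least 70757-fold higher at 8.97 ± 0.87 and was detected in 85% of ZsGreen-positive cells. Calca, which encodes calcitonin gene-related peptide and is also a locus that drove the sort, was higher by 15.83 ± 1.60 on the log2 scale (SE; adjusted p = 0.000144) and was detected in 98% of these cells. Ddc, the decarboxylase of serotonin and dopamine synthesis, had 2 counts outside the NE sort and a ratio of 62418 (17279 to 515420).

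Of the other higher genes named, Aplp1, a relative of the amyloid precursor, was at least 19515-fold higher, Upp1, a uridine phosphorylase, at least 19060-fold, Disp2 at least 14049-fold, and Sez6l2, a neuronal membrane protein, at least 6461-fold. Unc80, a subunit of a sodium leak channel, had a ratio of 51233 (9195 to 2023600) and Zcchc18 a ratio of 93910 (16854 to 3709300), each on 1 count outside the NE sort. Kcnip1, a potassium channel partner, had a ratio of 45511 (12598 to 375810) on 2 counts. Zcchc12 was higher by 14.74 ± 1.57 (adjusted p = 0.000197).

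Of the genes lower in the NE sort, 12 are named. Lyz2 and Lyz1, the lysozymes, were lower by log2 values of -9.28 ± 2.18 and -8.44 ± 1.81 (SE), and Slc34a2, the AT2 phosphate transporter, by -9.33 ± 2.02. Lyz2 was detected in 8% of ZsGreen-positive and 81.6% of ZsGreen-negative cells. The ZsGreen-positive sums include the 8 cells given a pair of types. Lyz2 had a mean TPM of 53.4 in that sort but 0.46 in the 92 NE cells, and Dynlrb2 13.5 but 0.44. Dynlrb2, a dynein light chain of cilia, had -8.97 ± 1.86, Lrrc23, a radial spoke protein, -8.35 ± 2.02, and Tmem212 -7.98 ± 1.71. Gipc2 had the lowest fitted value, -12.02 ± 1.45 (adjusted p = 0.000482), and the oxidase gene Aox3 had -10.42 ± 1.5. Chil1, a chitinase-like secreted protein, had -9.37 ± 2.00, and Lcn2, an antibacterial siderophore-binding protein, -8.04 ± 2.11. Hdc, which makes histamine, had -8.88 ± 1.69, and the lipid-binding Sec14l3 -7.94 ± 1.61. The adjusted p of these 12 genes ran from 0.000482 to 0.0466.

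The fixed lists were then counted in the NE sort. Of 16 dense core granule genes tested, 10 rose and 0 fell, among them Chgb by 13.91 ± 1.37 and Pam, the peptide-amidating enzyme, by 3.04 ± 0.46, and all 16 rose when adjusted over the list alone. Of 16 synaptic vesicle genes, 8 rose (11 adjusted over the list alone), including Snap25 by 8.38 ± 0.72 (adjusted p = 7.37e-05) and Cplx2 by 4.21 ± 0.65. NE markers rose in 14 of 16 cases, all 16 adjusted over the list alone; Ascl1, the transcription factor of the NE fate and a driver of the sort, rose by 11.67 ± 1.18 and Ncam1 by 4.58 ± 0.61. Among 11 neuropeptide genes 3 rose, Calca, Calcb and Cartpt, and adjusted over the list alone 4 rose and 3 fell. Calcb was at least 53170-fold higher and Cartpt at least 2085-fold. Of 8 small transmitter genes 2 rose (3 adjusted over the list alone), Ddc and Gad1, the enzyme that makes GABA, which was at least 8721-fold higher. Of 11 sensory genes 2 rose and 2 fell (4 and 3 adjusted over the list alone): the stretch-gated channel Piezo2 by 8.0 ± 0.76 and the potassium channel Kcnk3 by 6.83 ± 0.93, while Epas1, a hypoxia-inducible factor, had -5.08 ± 1.25 and Piezo1 a ratio of 5317 (954 to 210040) in favour of the other cells on 1 count in the ZsGreen-positive sort.

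Of 14 AT2 markers 8 fell (13 adjusted over the list alone), such as Sftpa1 at -7.27 ± 1.42 and Sftpb at -7.18 ± 1.68. Of 16 ciliated markers 6 fell (14 adjusted over the list alone), with Spag6 at -8.99 ± 1.49 and Foxj1, the master regulator of motile cilia, at -7.94 ± 1.83. Of 9 club markers 1 fell, Gsta3 at -6.95 ± 1.33 (8 adjusted over the list alone), and of 9 AT1 markers 1 fell, Clic5 at -4.52 ± 1.09 (5 adjusted over the list alone). Of 7 MHC class II genes 1 fell, H2-Aa at -11.34 ± 1.68 (5 adjusted over the list alone). Neither stress nor proliferation genes passed: 0 of 15 and 0 of 12 by edgeR (2 stress and 0 proliferation genes fell adjusted over the list alone), with Ier3 at -5.59 ± 1.57 (adjusted p = 0.0627) and Ccnb2 at -6.15 ± 1.93 (adjusted p = 0.0943). None of the 2 stromal, 1 basal, 1 tuft, 2 ionocyte, 3 immune and 1 endothelial markers tested passed; adjusted over the list alone, 1 tuft marker (Dclk1) and 1 immune marker (Cd14) fell. No erythroid marker had enough counts to be tested.

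Genes of the pathways in the series' title were mixed. Ccnd2, a D-type cyclin that drives inactivation of Rb, was the only 1 of 17 Rb pathway genes to pass (also adjusted over the list alone): it rose by 4.36 ± 0.51 (adjusted p = 0.000377) and was detected in 100% of ZsGreen-positive and 60.8% of ZsGreen-negative cells. Rb1 itself had 1.04 ± 1.59. Of 10 Notch ligands and antagonists, Dner, a non-canonical ligand, was at least 12445-fold higher and Dll4 at least 3142-fold higher, while Jag1 had -2.63 ± 0.60 (adjusted p = 0.0225); adjusted over the list alone, 3 rose and 1 fell. Of 6 Notch receptors and targets 0 passed by edgeR, and 3 fell adjusted over the list alone: Notch1 at -7.13 ± 2.00 (adjusted p = 0.0626 over all genes), Hes1, the main Notch target, at -6.63 ± 1.90 (0.068), and Notch2 at -3.15 ± 1.23 (0.193). Of 17 genes of p53 and its targets 0 passed, nor did any adjusted over the list alone; Trp53 had 0.26 ± 1.34 and Cdkn1a 0.43 ± 0.57. Of 9 small cell lung cancer genes only Ascl1 rose, also adjusted over the list alone.

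In all, edgeR's quasi-likelihood test with BH adjustment called 649 of 13198 genes between the sorts, 404 of them lower and the rest higher in the NE sort. Most rounds hold only one sort, and with round as a block, which leaves Ascl1 rounds 1 and 2 to carry the comparison, 6 genes were called, 2 higher and 4 lower, with 940 at an unadjusted p under 0.05. DESeq2 called 1732 genes and limma on TPM 1501. Without the 8 cells given a pair of types edgeR called 870 genes, 269 higher and 601 lower. Leaving out CGRP round 5 gave 895 calls, 652 of them lower, and leaving out Ascl1 round 2 gave 465, 334 of them lower.

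AT2 cells were the most numerous comparison type, with 54 cells. Pcsk1 was at least 58437-fold higher in NE cells (n = 7 rounds) than in AT2 cells (n = 3 rounds), Scg2 at least 31361-fold, Spock3, a proteoglycan, at least 19202-fold and Rab3b, a vesicle GTPase, at least 12321-fold; Calca had a ratio of 139710 (38675 to 1153600) on 2 counts in AT2 cells. Il33, an alarmin cytokine, had 1 count in NE cells and a ratio of 321240 (57656 to 12689000) in favour of AT2 cells. Lcn2 was at least 51977-fold lower in NE cells and Rai14 at least 19194-fold lower. Gja1, the gap junction protein connexin 43, had -16.25 ± 2.24 (SE; adjusted p = 0.00056), and Sfta2, a surfactant-associated protein, a ratio of 92766 (16649 to 3664100) in favour of AT2 cells.

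AT2 markers fell in 11 of 14 cases against AT2 cells (13 adjusted over the list alone), Cxcl15 by -12.45 ± 1.28 and Sftpc by -13.87 ± 1.99 on the log2 scale. MHC class II genes, which AT2 cells are known to carry, fell in 5 of 7 cases (all 7 adjusted over the list alone), with H2-Aa at -14.39 ± 2.33 and Cd74 at -12.09 ± 2.05. Some markers of types that neither group should hold fell too: 6 of 14 club markers (8 adjusted over the list alone; Cbr2 -11.08 ± 1.00), 5 of 16 ciliated markers (10; Pifo -12.64 ± 0.88) and 5 of 9 AT1 markers (6; Clic5 -6.67 ± 1.08). AT2 cells detected a mean of 6.04 of the 14 club markers and NE cells 2.15, and 6 AT2 cells of Lyz2 round 1 carried ciliated (4) or stromal (2) markers. Of 16 dense core genes 7 rose (all 16 adjusted over the list alone; Pam 3.93 ± 0.62), of 18 synaptic genes 5 (10; Snap25 7.71 ± 1.33), of 16 NE markers 10 (15; Ddc with a ratio of 26184, 7248 to 216220), of 15 neuropeptide genes 2 with 1 lower (4 and 2; Npw -7.25 ± 1.89), of 10 transmitter genes 2 (3 and 1 lower; Gad1 at least 3991-fold higher), and of 12 sensory genes 2 with 3 lower (3 and 4; Kcnk3 7.95 ± 1.17, Epas1 -6.94 ± 1.15). Among proliferation genes 2 of 17 fell (3 adjusted over the list alone), Bub1 at -7.65 ± 1.96 and Rrm2 at -7.81 ± 2.11, each detected in 3.70% of AT2 cells. Stress genes passed in 0 of 15 cases by edgeR, and in 0 adjusted over the list alone. Cftr of the ionocyte list and Cd14 and Csf1r of the immune list fell, also adjusted over the list alone; 0 stromal, basal, tuft, endothelial and erythroid markers passed, and adjusted over the list alone 2 basal and 2 tuft markers fell. Of 11 small cell lung cancer genes Ascl1 alone rose against each of AT2, ciliated and club cells, also adjusted over the list alone.

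Between NE and AT2 cells 805 of 15344 genes were called by edgeR with BH adjustment, 642 of them lower and the rest higher in NE cells. DESeq2 split its 1907 calls into 1001 higher and 906 lower, limma on TPM gave 438 and 440, and a minimum of 5 cells per sum 658, of which 435 were lower. With round as a block 5 genes were called, 1 higher and 4 lower (1719 at an unadjusted p under 0.05). Without Ascl1 round 2 there were 437 calls and without Lyz2 round 1 there were 400.

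Against ciliated cells, the genes Lrrc23, Tctex1d4, Vwa3a, Tsnaxip1 and Efhc1 had 0 counts in NE cells and were at least 55009-, 32059-, 24316-, 24081- and 22214-fold lower. Resp18, an endocrine granule protein, was at least 125330-fold higher in NE cells, Pcsk1 at least 41349-fold, Scg5, the chaperone of the prohormone convertase Pcsk2, at least 29921-fold, Scg2 at least 22191-fold and Ptprn, a granule membrane phosphatase, at least 14953-fold.

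Of 16 ciliated markers 13 fell (all 16 adjusted over the list alone), such as Pifo at -15.28 ± 0.93 and Dynlrb2 at -14.22 ± 1.17. Of 16 NE markers 15 rose, of 16 dense core genes 11 and of 18 synaptic genes 9 (15, 15 and 14 adjusted over the list alone), with Snap25 at 7.46 ± 1.15 and Rab3c at 5.93 ± 0.90. Of 15 neuropeptide genes 4 rose and 1 fell (5 and 3 adjusted over the list alone), with Calca at 15.06 ± 1.66 and Adm at -6.70 ± 1.65, and of 10 transmitter genes 2 rose (3), with Ddc at least 12352-fold higher. Of 12 sensory genes 3 rose and 1 fell (4 and 3 adjusted over the list alone), with Piezo2 at 11.26 ± 1.43 and Kcnk1 at 7.29 ± 1.33. Club markers fell in 6 of 14 cases (8; Cyp2f2 -13.22 ± 1.24) and AT1 markers in 4 of 9 (5; Hopx -7.59 ± 1.62), and ciliated cells detected a mean of 7.47 of the 14 club markers. Of 14 AT2 markers 2 fell and 1 rose (5 and 1), with Cxcl15 at -4.73 ± 0.97 and the membrane mucin Muc1 at 5.62 ± 1.24. Stress genes fell in 2 of 15 cases (5; Ier3 -5.70 ± 1.5, Fos -2.53 ± 0.70), and 1 member each of the stromal (Pdgfra -8.88 ± 2.29), basal (Trp63), tuft (Ltc4s), immune (Cd14), MHC class II (H2-Eb1), proliferation (Rrm2 -8.01 ± 2.09) and p53 (Phlda3 -9.39 ± 2.22) lists fell. Adjusted over each list alone, 8 stromal, 3 basal, 1 tuft, 2 immune, 5 MHC class II, 1 proliferation and 2 p53 genes fell, and 1 p53 gene and 1 erythroid marker rose. No ionocyte or endothelial marker passed. A few cells hold much of this: 1430 of the 1431 Trp63 counts of ciliated cells were in the Ascl1 line, where 1 cell assigned as ciliated had a TPM of 417 against at most 0.15 in the others, and 2394 of 2397 Pdgfra counts were in the Lyz2 line, where 3 ciliated cells of round 1 carried stromal markers; the median stromal score of ciliated cells was 0.22 and the highest 5.32.

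edgeR called 1187 of 15344 genes between NE and ciliated cells, 357 higher and 830 lower in NE cells (n = 7 and 4 rounds). DESeq2 split 2614 calls into 1333 higher and 1281 lower. The block on round left 24, of which 6 were higher and 18 lower (1744 at an unadjusted p under 0.05). Leaving out Ascl1 round 2, Lyz2 round 1 or Lyz2 round 2 gave 624, 646 and 685, and a minimum of 5 cells per sum gave 765.

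Against club cells, Reg3g, a secreted antibacterial lectin, had 2 counts in NE cells and a ratio of 750060 (207630 to 6193500) in favour of club cells. Cd14, an endotoxin receptor, Retnla, a resistin-like cytokine, Pon1, a lactonase, and Fmo3, a flavin monooxygenase, had 0 counts in NE cells and were at least 58641-, 50852-, 43718- and 39858-fold lower. Resp18 was at least 32079-fold higher in NE cells, Calca at least 16868-fold, Pcsk1 at least 10584-fold, Scg5 at least 7659-fold and Zcchc12 at least 4801-fold.

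All 14 club markers fell against club cells, also adjusted over the list alone, with Cyp2f2 at -15.46 ± 1.35 and Cbr2 at -12.73 ± 1.07. Ciliated markers fell in 8 of 16 cases (12 adjusted over the list alone; Pifo -12.81 ± 0.90), AT2 markers in 5 of 14 (10; Cxcl15 -9.60 ± 1.19) and AT1 markers in 4 of 9 (5; Clic5 -7.20 ± 1.14). NE markers rose in 12 of 16 cases (15), dense core genes in 8 of 16 (12), and synaptic genes in 6 of 18 (10), with Snap25 at 10.06 ± 1.8. Of 15 neuropeptide genes only Calca rose (2 rose and 1 fell adjusted over the list alone), and of 10 transmitter genes Ddc rose, at least 3162-fold, and Tph2 fell. Of 12 sensory genes 2 rose and 3 fell (2 and 4), with Kcnk3 at 8.61 ± 1.48 and Epas1 at -7.61 ± 1.22. A single member each of the stress (Ier3 -6.53 ± 1.64), MHC class II (Cd74 -7.37 ± 1.81), ionocyte (Cftr -10.19 ± 1.84) and immune (Cd14) lists fell, with the same counts adjusted over the list alone. No stromal, basal, tuft, endothelial, erythroid or proliferation gene passed; adjusted over the list alone 6 stromal, 1 basal and 1 endothelial marker fell.

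Between NE and club cells edgeR called 685 of 15344 genes, 89 higher and 596 lower in NE cells, from 7 NE rounds and 2 club rounds. DESeq2 gave 1190 higher and 779 lower, limma on TPM 618 and 251. The block on round gave 8 calls, 0 higher and 8 lower (1141 at an unadjusted p under 0.05), an indirect value since no round holds sums of both types. The count fell to 35.2% of this without Lyz2 round 1 and was 362 without Lyz2 round 2, each of which leaves 1 club round that is assumed to vary like the other types.

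Genes above all of the other types were sought next. Of the 72 NE-enriched genes 12 are named, in the order of their fitted values and not of these bounds: Pcsk1, at least 10584-fold above each of AT2, ciliated and club cells, Scg2 (at least 5680-fold), Upp1 (at least 1424-fold), Aplp1 (at least 1553-fold) and Dner (at least 1014-fold). Calca (at least 16868-fold), Sez6l2 (at least 505.3-fold), Ddc (at least 3162-fold), Zcchc12 (at least 4801-fold), Disp2 (at least 988-fold), Tcerg1l (at least 1574-fold) and Unc80 (at least 1374-fold) completed the 12, each bound being the smallest of the 3, against club cells. NE markers gave 10 of the genes, dense core genes 5 (Chga, Chgb, Pcsk1, Resp18, Scg2) and synaptic genes 5 (Cplx2, Rab3b, Rab3c, Snap25, Syt4). The lists overlap: these 5 dense core genes, with Snap25, Calca and Ddc, are also among the 10 NE markers. Piezo2 and Kcnk3 of the sensory list, Dner of the Notch ligands, Ccnd2 of the Rb list, Calca of the neuropeptides and Ddc of the transmitter list were enriched, and 0 of 19 p53 genes.

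**Figure D2:**
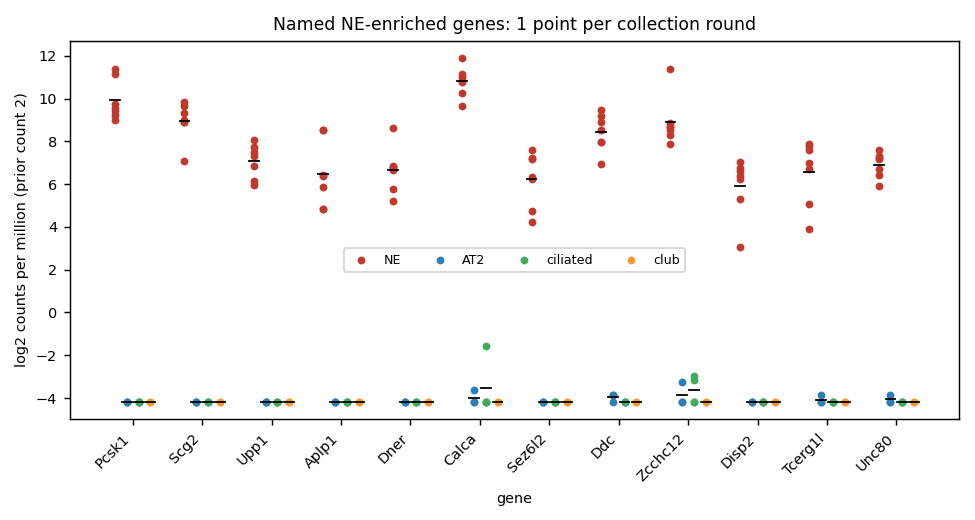
Log2 CPM (prior count 2) on the y axis for the 12 named NE-enriched genes on the x axis, with 1 point per collection round coloured by assigned type and a bar at the mean over rounds. The 7 NE rounds stand above every round of the other types for each gene; Pcsk1, Scg2 and Upp1 have 0 counts in AT2, ciliated and club cells.

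There were 307 NE-depleted genes, below AT2, ciliated and club cells alike. In NE cells 0 counts were found of Osgin1, an oxidative stress response gene, Rnf186, a ubiquitin ligase, Lrrc23, Gipc2, Acox2, a peroxisomal oxidase, and Rai14, which were at least 7663-, 6236-, 4093-, 3579-, 3570- and 2405-fold lower than in each other type. These bounds are on summed counts, which a minority of cells can carry. Lrrc23 was detected in 29.6% of AT2 and 23.5% of club cells, and Gipc2 in 24.1% of AT2 cells. Rai14 stood at -3.14 log2 CPM in ciliated cells of Ascl1 round 1, near the -4.17 of sums without counts. Pdlim1, Drc1, Ccdc113 and Calml4 had 1 count in NE cells and Cyp4b1, a cytochrome P450 of club cells, had 3. Cyp2b10, another P450, had -12.71 ± 1.08 against AT2, -14.62 ± 1.13 against ciliated and -13.91 ± 1.13 against club cells. By list, 5 of 14 club, 4 of 16 ciliated, 3 of 9 AT1 and 2 of 14 AT2 markers were depleted, with Cd14 of the immune list, Epas1 of the sensory list, and Hes1 and Notch1 of the Notch receptors and targets. The AT1 marker Aqp5 had 1740 counts in ciliated cells of the Ascl1 line and 20 in the Lyz2 line. A single cell assigned as ciliated held it at a TPM of 606, against at most 4.52 in the others, so its ciliated level rests largely on that cell. Of the depleted genes 56 had their highest mean TPM in AT2 cells, 18 in club cells and the rest in ciliated cells.

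The 3 comparisons behind each set share their NE rounds. If the 3 lists of calls were independent, 0.022 genes would be enriched and 1.35 depleted, and 5 simulations of unchanged groups gave at most 0. That 0 was likely in advance, since edgeR called 0 of 14819 unchanged genes against club cells in the other simulated data. Neither value covers genes that differ from a single type and are tested 3 times with the same NE rounds. Nothing is concluded from them on chance. With the NE rounds divided into 3 sets, one for each comparison, 23 genes were enriched and 37 depleted, all shared with the full sets; that division was chosen after the data had been seen. With round as a block, indirect for club cells, 0 genes were enriched by edgeR and 4 depleted. DESeq2 gave 395 and 450. limma on TPM gave 90 depleted genes, 29.4% of both sets together against 81% here. Without Lyz2 round 1 there were 19 enriched genes and 34.2% of the depleted count, and without Lyz2 round 2 there were 21 and 58.3%.

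As groups, NE markers, dense core genes and synaptic vesicle genes stood above all other genes in NE cells against the mean of AT2, ciliated and club cells (camera, adjusted p = 8.68e-32, 7.93e-28 and 1.49e-16; 1.46e-05, 1.46e-05 and 4.95e-05 with an estimated correlation). Ciliated markers (8.87e-18) and club markers (5.36e-10) stood below, with adjusted p = 0.00386 and 0.00204 with an estimated correlation; with round as a block as well, these calls were lost at adjusted p = 0.0964 and 0.0843. Notch receptors and targets also stood lower in NE cells (adjusted p = 0.000232; adjusted p = 0.00535 with an estimated correlation; 0.0247 with round as a block, a call lost at adjusted p = 0.253 with an estimated correlation). AT2 markers (0.000312), AT1 markers (0.000488) and MHC class II genes (0.000488) stood lower, calls that were lost at adjusted p = 0.152, 0.140 and 0.0683 with an estimated correlation; with round as a block AT1 markers gave 0.133. The small transmitter list stood higher and the stress list lower, both at adjusted p = 0.0269, and these were lost at adjusted p = 0.0683 and 0.261 with an estimated correlation. With round as a block the stress list ranked above other genes (adjusted p = 0.601) although its median log2 value was still below 0 at -0.20. Lists that did not pass were neuropeptides (0.137), sensory channels (0.336), Notch ligands (0.137), the Rb pathway (0.926), p53 (0.479), proliferation (0.681), small cell lung cancer (0.280), stromal (0.168), basal (0.158), tuft (0.344), ionocyte (0.374) and immune markers (0.0652). Endothelial and erythroid markers were too few to test. The types were assigned from the expression of these cells, and Ascl1 and Calca drove the sort. The direction of the NE, AT2, ciliated and club marker lists was therefore favoured in advance. The NE list also shares genes with the dense core list, such as Chga, and the synaptic list, such as Snap25, so their results are not independent.

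The series' title names Notch, Rb and p53, and the share of cells with their transcripts was therefore read per type. Hes1 was detected in 6.52% of NE cells (95% interval 2.43 to 13.7) against 83.3% of AT2, 95.3% of ciliated and 52.9% of club cells, and it was lower in NE cells by -8.20 ± 1.49, -9.33 ± 1.52 and -8.43 ± 1.54 on the log2 scale (adjusted p = 0.00379, 0.00128 and 0.00427). Notch1 was detected in 1.09% of NE cells and was lower than in AT2 (-6.64 ± 1.8), ciliated (-8.05 ± 1.86) and club cells (-8.50 ± 1.97), and Notch2 was detected in 18.5% (11.1 to 27.9) and was lower than in club cells (-5.03 ± 1.18). Of 7 such genes tested, 2, 2 and 3 fell against AT2, ciliated and club cells (3, 4 and 4 adjusted over the list alone). Rbpj, which joins Notch to DNA, was found in 60.9% of NE cells, within the range of the other types (52.9% to 69.8%). Dner was detected in 50% of NE cells (39.4 to 60.6) and in 0 of the AT2, ciliated and club cells, and it rose against all 3 types. Of 12 ligands tested, 1, 2 and 1 rose, and Jag1 fell against ciliated cells (-4.02 ± 0.81); adjusted over the list alone 2, 2 and 1 rose, and 1 fell against each of AT2 and ciliated cells. Dll1 was found in 21.7% of NE cells and Dll3 in 39.1%.

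Ccnd2 was detected in 100% of NE cells (96.1 to 100), 50% of AT2, 67.4% of ciliated and 52.9% of club cells, and rose by 4.57 ± 0.92, 3.85 ± 0.77 and 4.55 ± 1.11. It was the 1 of 21 Rb pathway genes that rose against each type, also adjusted over the list alone; Cdkn2b, with 2 counts in NE cells, fell against AT2 and ciliated cells. Rb1 was detected in 30.4% of NE cells (21.3 to 40.9) against 9.26%, 30.2% and 11.8%, Cdkn1b, an inhibitor of cyclin-dependent kinases, in 92.4%, and Ccnd1 in 65.2%. Trp53 was detected in 31.5% of NE cells (22.2 to 42) and in 27.9% to 40.7% of cells of the other types, Cdkn1a in 72.8% and Mdm2 in 54.3%. Of 19 p53 genes 0 passed against AT2 and club cells by edgeR, nor adjusted over the list alone. Mki67, a marker of cycling cells, was detected in 2.17% of NE cells and 22.2% of AT2 cells. The list as a whole did not follow it: 9 of 17 proliferation genes tested had values above 0 in NE against AT2 cells, with a median log2 value of 0.05. Against the mean of AT2, ciliated and club cells the list did not pass (camera, adjusted p = 0.681). A TPM of at least 1 depends on depth, and NE cells had a median of 2259790 gene counts against 3716060 in AT2 cells. At this threshold 9 of the 67 Notch, Rb and p53 genes were detected in at least 50% of NE cells, 5 at a TPM of at least 5 and 14 at any TPM above 0. In the cells that could be thinned to 1109900 gene counts each, without 14 NE cells, 12 genes were. There 1 count was taken as detection, so the 12 and the 9 are not at the same threshold.

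**Figure D3:**
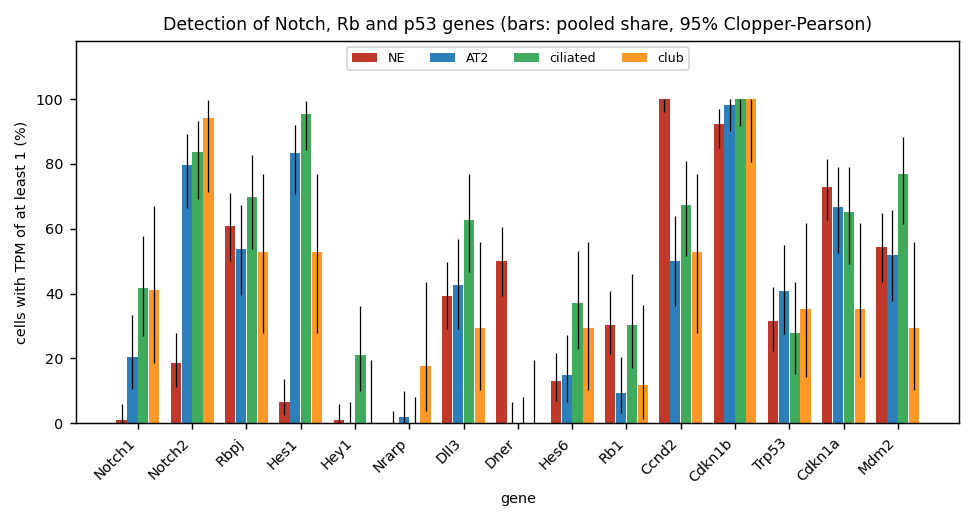
Percent of cells with a TPM of at least 1 on the y axis for Notch, Rb and p53 genes on the x axis, with bars for NE, AT2, ciliated and club cells and lines for exact 95% Clopper-Pearson intervals. Hes1 stands at 6.52% in NE cells and at least 52.9% elsewhere, while Ccnd2 reaches 100% in NE cells.

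AT2 and ciliated cells were compared with each other because they share rounds. AT2 cells were higher in Il33 (13.64 ± 1.84, SE; adjusted p = 0.0072), Bex2 (11.11 ± 1.58), the potassium channel Kcnj15 (7.09 ± 1.18), the transcription factor Tfcp2l1 (5.30 ± 0.76) and Npc2, a cholesterol carrier (4.65 ± 0.70), and ciliated cells in the surface glycoprotein Cd24a (-3.41 ± 0.47). edgeR with BH adjustment called 8 of 15344 genes, 7 higher in AT2 cells (n = 3 rounds) and 1 higher in ciliated cells (n = 4 rounds), with 1643 at an unadjusted p under 0.05. Of the AT2 and ciliated markers 0 passed over all genes, with Cxcl15 at 7.72 ± 1.39 (adjusted p = 0.0665) and Pifo at -2.63 ± 0.80 (adjusted p = 0.313), and adjusted over the list alone 12 AT2 markers rose and 4 ciliated markers fell. DESeq2 called 831 genes (447 higher, 384 lower), limma on TPM 509 (335 lower and the rest higher), ERCC scaling 3 (3 higher, 0 lower), and the block on round 0. The count was 0 without Ascl1 round 1 or 2, 5 without Lyz2 round 2, and 33 without the 15 cells whose markers pointed to another type, an alternative chosen after the data had been seen.

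NE cells labelled through Ascl1 (n = 2 rounds, 8 cells) and through CGRP (n = 5 rounds, 84 cells) were compared to see whether the drivers mark cells that differ. AT2 markers stood higher in Ascl1-labelled NE cells as a group (camera, adjusted p = 3.13e-05; adjusted p = 0.104 with an estimated correlation), with Sftpb at 7.44 ± 2.11 and Sftpc at 5.97 ± 1.93, neither past the test by itself (adjusted p = 0.389 and 0.396). Stress genes also stood higher (adjusted p = 0.00266; adjusted p = 0.798 with an estimated correlation), with Hspa1b at 10.48 ± 2.89 and Hsp90aa1 at 1.08 ± 0.30. NE cells of Ascl1 rounds 1 and 2 detected a mean of 7.5 and 4.17 of the 14 AT2 markers, against 1.11 to 2.75 in the CGRP rounds. Only the Ascl1 rounds held NE and AT2 cells together, and their ciliated cells detected 7.5 and 3.57 of these markers, so driver and round are not separated here. edgeR, which in simulated data of this comparison called 3.08% of genes changed 64-fold, called 0 of 12638 genes, with 1541 at an unadjusted p under 0.05, limma on TPM 0, and DESeq2 1820, of which 1632 were lower. No list had a member that passed over all genes; adjusted over the list alone, 2 stress genes and 1 p53 gene were higher and 1 p53 gene and 1 ciliated marker lower in Ascl1-labelled NE cells.

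Ciliated cells of the Lyz2 line and the Ascl1 line (n = 2 rounds each) were also compared. edgeR called 0 of 11531 genes, with 1322 at an unadjusted p under 0.05, but with 2 residual degrees of freedom it called only 11.7% of genes changed 64-fold in simulated data, so large differences could have been missed. limma on TPM called 0 and DESeq2 1265, 1174 higher in the Lyz2 line and 91 lower. No gene list had a member past the test, also adjusted over the list alone.

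The Lyz2 line was meant to remove AT2 cells from the ZsGreen-negative sort. AT2 cells made up 84.6% of these cells in Ascl1 round 1 (22 of 26; exact Clopper-Pearson interval 65.1 to 95.6), 38.5% in Ascl1 round 2 (5 of 13; 13.9 to 68.4), 41.9% in Lyz2 round 1 (26 of 62; 29.5 to 55.2) and 4.17% in Lyz2 round 2 (1 of 24; 0.105 to 21.1). The means of the lines were 61.5% ± 32.6 and 23.1% ± 26.7 (SD, n = 2 rounds each), a difference of 38.5 points (two-sided exact permutation test over 6 splits, p = 0.667; the smallest possible p is 0.33, so no difference could pass). It was 15.4 points without Ascl1 round 1 and 61.6 points without Ascl1 round 2.

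The amount of cellular RNA against the spike-in did not separate NE cells from other types. Round medians of the log2 ratio of gene to ERCC counts had a mean of 1.42 ± 0.56 in NE cells (SD, n = 7 rounds), 1.30 ± 0.56 in AT2 cells (n = 3), 0.75 ± 0.82 in ciliated cells (n = 4) and 1.66 ± 1.20 in club cells (n = 2). NE cells differed from AT2 cells by 0.12 (two-sided exact permutation p = 0.742, adjusted over 3 comparisons 0.742; smallest possible p = 0.00833), from ciliated cells by 0.67 (exact permutation p = 0.139, adjusted 0.418; smallest 0.00303) and from club cells by -0.24 (exact permutation p = 0.667, adjusted 0.742; smallest 0.0278). Within Ascl1 round 1 NE cells differed from AT2 cells by -0.13 and from ciliated cells by -0.01, and within Ascl1 round 2 by -0.22 and 0.62. Whether each round received the same amount of spike is not given in the sources used here.

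**Figure D4:**
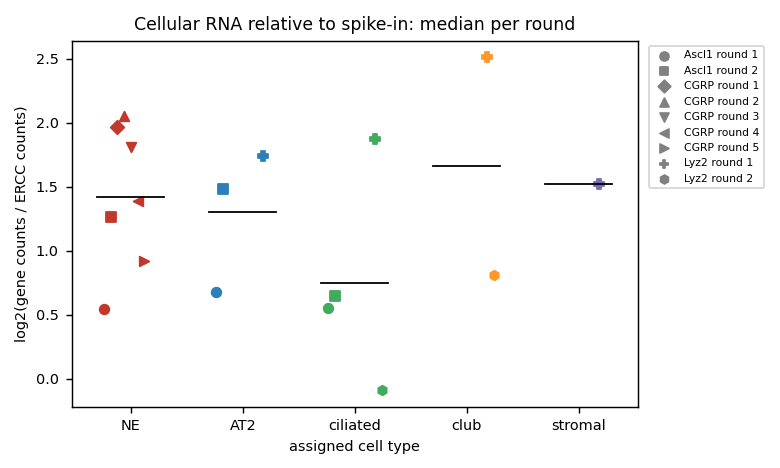
Log2 ratio of gene counts to ERCC counts on the y axis by assigned type on the x axis, with 1 point per round (its median over cells, the shape naming the round) and a bar at the mean over rounds. NE rounds average 1.42 and ciliated rounds 0.75, and rounds of each type with several rounds spread widely.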

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

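Each measure was searched for a round far from the others by Dixon's rule, applied as fixed before the data were examined, and no test in this part was chosen after its result was seen. Of 38 groups of rounds, 7 had such a round. Chance gives about 1 in 20 in general, but that rate does not apply to the 4 shares with 0% in every other round, where any cell meets the rule, so 7 of 38 is not read as an excess.

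Stromal cells made up 17.7% of the ZsGreen-negative cells in Lyz2 round 1 and 0% in the other rounds. Scg2, the granin gene, stood at 7.09 log2 CPM in the NE sort of CGRP round 2, below the other rounds (8.89 to 9.72). Zcchc12 stood at 11.05 log2 CPM in Ascl1 round 1, above the other rounds (7.91 to 8.91). Hes1 was detected in 22.2% of NE cells of CGRP round 1 and in at most 7.14% elsewhere. Other Notch genes were each detected in NE cells of a single round: Hey1 in 16.7% in Ascl1 round 2, Notch4 in 11.1% in CGRP round 1 and Notch1 in 2.38% in CGRP round 5, with 0% in the other rounds of at least 4 cells. These shares rest on 1 or 2 cells each.

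Signals were also present outside the comparisons. The ZsGreen transcript reached a TPM of at least 1 in 43 ZsGreen-negative cells, 16 of 39 from the Ascl1 rounds and 27 of 86 from the Lyz2 rounds, and 23 of them exceeded a TPM of 100. The 11 stromal cells, which entered no comparison, had a median stromal marker score (the mean log2(TPM + 1) of the list) of 5.19, against 0.15 in NE cells, although the sort was for the epithelial protein EpCAM.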

How the results depend on the processing

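Alternatives were fixed before the data were examined except the removal of 15 cells whose markers pointed to another type and the division of NE rounds into 3 sets, which were chosen after the results were seen.

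DESeq2 called 1732 genes between the sorts, 1907, 2614 and 1969 for NE against AT2, ciliated and club cells, 831 for AT2 against ciliated cells, 395 NE-enriched genes, 1820 by driver and 1265 by line of ciliated cells; 634 of the 649 calls between the sorts were shared. On simulated data it called unchanged genes (1.75% between the sorts, 2.54% by driver); whether that is the cause here was not tested. limma on TPM called 1501 genes between the sorts (539 higher, 962 lower), 509 for AT2 against ciliated cells, 2.2e+02 NE-enriched and 90 NE-depleted genes; the cause was not tested. A minimum of 5 cells per sum gave 765 calls for NE against ciliated cells, from fewer sums. ERCC scaling gave 3 for AT2 against ciliated cells; the cause was not tested.

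With round as a block 6 genes were called between the sorts (3 shared), 5, 24 and 8 for NE against AT2, ciliated and club cells, 0 for AT2 against ciliated cells, 0 NE-enriched and 4 NE-depleted; the block leaves fewer rounds to estimate each difference, and values with club cells are indirect, since no round holds both. The stress list ranked above other genes (adjusted p = 0.601), with a median still below 0, and it and the AT1 list lost their calls; with an estimated correlation only the NE, dense core and synaptic lists were called under the block. Of the 110 gene results called here and named, 2 kept their call under the block. Some differences stayed large: Pcsk1 stood at 11.40 and 9.25 log2 CPM in NE cells of Ascl1 rounds 1 and 2 with 0 counts in AT2 and ciliated cells, and the median log2 value of the NE list was 11.55 against 12.14. Others shrank: the list median was -6.24 against -8.37 for AT2 markers and -2.93 against -6.33 for AT1 markers. For stromal markers, called in neither fit, the list median was 0.45 against -2.67.

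Leaving out each round gave 465 to 895 calls between the sorts, 400 to 695 for NE against AT2, 624 to 968 against ciliated, 2.4e+02 to 624 against club, 0 to 11 for AT2 against ciliated, 19 to 83 NE-enriched, 1.1e+02 to 297 NE-depleted, and 0 by driver and by line throughout. The AT2 share difference ran from 15.4 to 61.6 points. Lyz2 round 1 gave the lowest NE against AT2, club and conjunction counts. Without the 15 cells AT2 against ciliated cells rose to 33 calls, and with NE rounds in 3 sets there were 23 enriched and 37 depleted genes; fewer rounds enter each of the latter, and the cause of the former was not tested. Lists passing camera went from 11 to 6 of 23 with an estimated correlation, and by driver from 2 to 0 of 18. RNA against ERCC moved to -0.13 (AT2) and -0.0085 (ciliated) within Ascl1 round 1 and -0.22 (AT2) within Ascl1 round 2; the cause was not tested. Genes detected in at least 50% of NE cells numbered 9, or 5 at a TPM of at least 5 and 14 above 0.

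Of the 110 named calls, 5 had no adjusted p from DESeq2, which kept the rest; 9 were lost with ERCC scaling, 0 with RLE or no filter, 3 with limma on TPM, and 1 to 22 without a round; none changed direction in these. In simulated data of the sorts edgeR called 31.3% of genes changed 64-fold.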

Other observations

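Tests on the excess of depleted genes and on cells given a pair of types were chosen only after the results were seen; those on the NE-depleted genes were fixed before their deciding values were, although shares of detection of some of these genes had been seen.

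Peptide genes were detected in different shares of NE cells at a TPM of at least 1, a level that the club cell gene Scgb1a1 reached in 87% of them. Calca was found in 98.9% of NE cells, Calcb in 44.6% and Cartpt in 29.3%, while Grp, the gene of gastrin-releasing peptide, was found in 0 of 92, which allows a share of up to 3.26%. Among transmitter genes Gad1 was found in 21.7% and Tph1, which starts serotonin synthesis, in 3.26%. Piezo2 was found in 100% of NE cells and in 9.26% of AT2, 2.33% of ciliated and 5.88% of club cells.

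Some cells assigned a single type had markers that pointed to another. In such a cell another type's marker score reached the 5th percentile of that type's own cells, or its own list did not score highest. There were 15 such cells, 14 of them in Lyz2 round 1 and 0 among the 92 NE cells. The 6 AT2 cells among them (4 with ciliated and 2 with stromal markers) lay above the AT2 median of their round in RNA against ERCC by a median of 0.76 on the log2 scale; the median difference from cells of their own type and round was 0.53 for the 4 ciliated, -0.61 for the 2 club and -0.10 for the 3 stromal cells. A cell of Ascl1 round 1 assigned as ciliated, picked out after its values were seen, detected no ciliated marker and held Trp63 at a TPM of 417, Krt15 at 230, Aqp5 at 606, Cav1 at 1316 and Pdpn at 452, with Krt5 and Epcam at 0.

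The NE-depleted genes, such as Hes1, Cyp2b10 and Ccdc113, were below AT2, ciliated and club cells together. Cells of a second type could have been caught with AT2, ciliated or club cells. The 15 cells do not by themselves account for the whole set: without them 2.2e+02 genes were called, 72% of 307, not far above the bound of 1 in 1.5 set for it. Weaker mixtures were not removed, so this cause is not excluded. Before the removal AT2 cells of Lyz2 round 1 detected a mean of 5.27 ciliated markers, against 1.59 in Ascl1 round 1. RNA of other cells in the same round stays open, since the median gene's lowest mean TPM among these types was 8.11% of its highest, with 36 genes under 2% and 1.3e+02 at 10% or more. Round stays open too, because CGRP rounds hold NE cells alone and 58.6% of the genes were lower in NE cells in both Ascl1 rounds. No biological explanation was tested.

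Depleted genes were 81% of both conjunctions together. A few abundant genes take much of the counts of AT2 and club cells and could act through the scaling. The share was then to fall with ERCC sums as library sizes, and it stayed at 79.1%, so it did not depend on TMM scaling. That change leaves the counts as they are, so it cannot decide whether fewer counts of other genes in AT2 and club sums play a part. The way a test treats groups with few counts could account for the excess: DESeq2 on the same sums gave 53.3% and limma on TPM 29.4%. Under DESeq2 both sets grew, the enriched from 72 to 395 genes and the depleted from 307 to 450. Its share thus fell through more enriched genes and not through fewer depleted ones. No biological explanation was tested.

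The cells given a pair of types could be 2 cells caught in 1 chamber: 7 of 8 lay above the NE median of their round in RNA against ERCC, with a median difference of 0.87 on the log2 scale (two-sided exact sign test, p = 0.0703). Most of the 8 cells came from CGRP round 5 and were set against the same median. The cell of Ascl1 round 1 was set against 2 NE cells. The sign test takes the cells as independent, which cells of the same round are not. RNA of other cells in the chamber fluid stays open. In 6 cells the second marker score exceeded that of every NE cell of single type, but the pairs were assigned from expression, so a high score was expected. The other 2 cells lay within the NE range, an NE and AT2 cell of CGRP round 1 and an NE and ciliated cell of Ascl1 round 1 whose ciliated score of 0.46 lay below the NE median of 0.57. A true mixed state stays open as well, since no test separates it from a captured pair.

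Other splits of the samples were compared with the real grouping, the real one included. Only 1 of 100 splits called as many genes between the sorts (649, highest other 28), the smallest share that 100 splits can give. A random grouping of the sums would thus rarely reach this count. The splits do not separate sort from round, since most rounds hold 1 sort, and with round as a block 6 genes were called. The share was 1 of 100 for NE against AT2 (805, highest other 19), 1 of 100 for NE against ciliated (1187, highest other 2) and 1 of 35 for AT2 against ciliated cells (8, highest other 3), but types were assigned from the expression tested, so the real split was favoured and nothing is concluded on chance there.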
